A study of Drosophila melanogaster with 12 samples.

How the data were processed

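RNA was measured in nuclear and cytoplasmic fractions of D. mel-2 cells, an embryonic cell line of Drosophila melanogaster, after RNA interference against U2AF50, the large subunit of the splicing factor U2AF, or after a non-specific RNA interference that served as the control. The 12 samples fell into 4 groups of 3 by their titles, which give the treatment, the fraction and a replicate number. Each sample was hybridised to a 1-colour Affymetrix array of the fly genome. The labels of part of the samples add that the fractions were made by hypotonic lysis. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

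The deposited values are intensities on a linear scale, 1 per probe set and array, for 14010 probe sets. Read from the values themselves, each deposited intensity column has a mean of 1000 once its lowest and highest 2% of probe sets are set aside, so the authors' scaling brought the arrays to a common level. The image software, the background correction and the way probes were summarised are not given in the sources used here. No further centring could be seen in the deposited intensities, whose medians on the log2 scale lay between 8.75 and 9.21.

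Because those medians spanned 0.46, the arrays were quantile normalised across all 12, by a rule fixed before the data were examined. Intensities were first turned into log2(value + 94.7), where 94.7 is the 20th percentile of all values. A change on this scale understates that of weakly expressed genes. The 44 Affymetrix control probe sets were left out, which left 13966, and probe sets whose mean over the arrays lay above the 40th percentile were tested, 8379 in all. The platform annotation gave 1 gene symbol for 12444 probe sets, several for 327 and none for 1239. Of these probe sets, 12394 were matched to current fly gene names through the gene identifier, and 0 symbols had to be updated. No gene was named from a probe set with several symbols.

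Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) over all 12 arrays, with 8 residual degrees of freedom and 8.9 from the prior. The Benjamini-Hochberg adjustment ran over the probe sets tested, and an adjusted p under 0.05 was the threshold. The 5 contrasts were nucleus against cytoplasm under each treatment, U2AF50 against non-specific RNA interference in each fraction, and the interaction, which is the change of the nucleus to cytoplasm ratio with U2AF50 depletion. Errors given with log2 changes are limma standard errors from 3 arrays a group. The number of arrays limits the precision.

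Gene lists chosen before the data were examined were tested with limma's camera, with a preset correlation between genes of 0.01, on 1 probe set per gene, the one with the highest mean, over 6868 genes. The adjustment ran over the 25 lists with at least 3 measured members, and smaller lists were only counted. The same test was run with the correlation estimated from the data. Member calls are given over all probe sets and, where they differ, adjusted over the list alone. Several probe sets were tested for 497 genes. Between the fractions under non-specific RNA interference, 160 out of 256 such genes with a call did not have all probe sets called, and 6 were called in both directions. Under U2AF50 RNA interference these were 195 out of 287, and 6. With depletion, not all probe sets were called for 25 out of 25 genes in the cytoplasm and 28 out of 31 in the nucleus. In the interaction it was 2 out of 2. In these 3 contrasts 0 genes were called in both directions.

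Named genes followed a rule fixed before the data were examined. They were U2af50 and U2af38, and for each contrast the 8 genes with the largest change in each direction among those past the threshold and well expressed, plus 2 in each direction known only by an annotation number. Outside the interaction, all 3 arrays of 1 group also had to lie above all 3 of the other. Up to 4 members of each list were named as well, those with the largest change. Genes outside the rule are marked as chosen after their values were seen.

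The procedure was tested on simulated arrays in which 200 of 8379 probe sets were changed. Each probe set had 1 spread, estimated from the real arrays and used for all 4 groups. For the shares given here, the depleted groups took the means of the control in the same fraction before the changes. The simulation therefore does not cover groups of unequal spread. For the treatment contrast in the cytoplasm, 94% of log2 changes of 3, 68% of changes of 2, 34% of changes of 1 and 0% of changes of 0.5 were recovered, and 8.4% of the calls were false. For the interaction the shares were 66%, 48%, 12% and 2%. In 100 simulated draws, camera gave an unadjusted p under 0.05 for a list of 30 genes shifted by 0.5 in 100% and for an unchanged list in 4%. The simulated genes varied independently of one another, so these draws do not give the false calls of lists whose genes are correlated.

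Alternatives covered the pseudocount, the filter, the scaling between arrays, the variance prior, the arrays in the fit, the replicate number as a block, the threshold, each array left out in turn and, for lists, the correlation and the choice of probe set. Covariates for RNA integrity (the ratio of the 3' to the 5' probe set of GAPDH) and for labelled RNA (the hybridisation controls) were added after the data had been seen. A planned test of all intronless genes needed exon annotation that was not used here, and only intronless genes listed by name beforehand were analysed. Transcripts encoded by the mitochondrial genome, with 0 members on the array, and nuclear noncoding RNAs, with 1, were not analysed here.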

Results

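The series title names the distribution of mRNA between nucleus and cytoplasm, and the samples set cells depleted of U2AF50 against control cells in both fractions. U2AF binds the 3' splice site of introns, and its large subunit has also been studied as a factor in mRNA export. Each of the 4 groups had 3 arrays. Median deposited intensities were 474, 404 and 372 for the control cytoplasm, 385, 436 and 401 for the control nucleus, 341, 335 and 344 for the U2AF50-depleted cytoplasm and 480, 497 and 426 for the U2AF50-depleted nucleus. Pairs of arrays of 1 group correlated across probe sets with r between 0.854 and 0.958, and no pair held identical values throughout. The depleted cytoplasm gave the closest pairs and the depleted nucleus the widest.

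The mRNA of the targeted gene, U2af50, fell in the cytoplasm of U2AF50-depleted cells to 29.8% of the control level (log2 change -1.75, SE 0.26, limma adjusted p = 0.0012, n = 3 per group). Its cytoplasmic intensities were 1030, 1327 and 1143 after U2AF50 RNA interference against 2474, 5606 and 4751 in the control, so all 3 depleted samples lay below all 3 controls. In the nucleus the intensities were 2718, 1738 and 1678 against 1701, 1710 and 1589, and the change did not pass the test (log2 change 0.21, SE 0.26, adjusted p = 0.7384). The difference between the fractions was itself past the threshold (interaction 1.96, SE 0.37, adjusted p = 0.0375), although it passed in only 9 of 25 alternative settings, where it lay between 1.58 and 2.28. U2af38, the small subunit of the same factor, had log2 changes of -0.12 in the cytoplasm (adjusted p = 0.8144) and -0.21 in the nucleus (adjusted p = 0.6513).

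**Figure D1:**
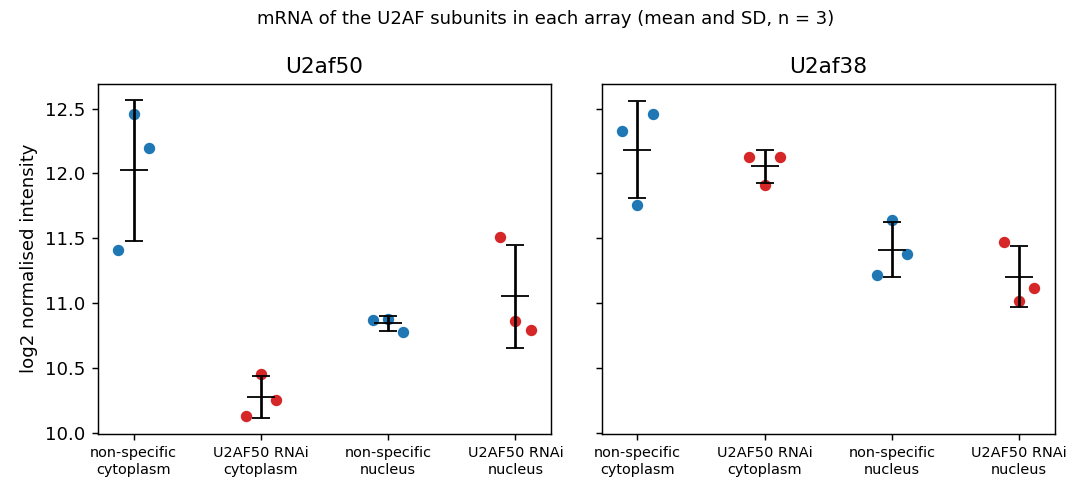
Log2 normalised intensity of U2af50 (left) and U2af38 (right) in each array, as points, with the mean and SD of the 3 arrays of a group. For U2af50 the depleted cytoplasm lies between 10.13 and 10.45, below every control cytoplasm array (11.41 to 12.46), while the nuclear arrays overlap.

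The first comparison asked which mRNAs lay in the nuclear or the cytoplasmic fraction of control cells. The largest nuclear excess among the named genes was that of Glt. This basement membrane glycoprotein gene was 58.7-fold higher in the nuclear fraction (log2 change 5.88, SE 0.3, n = 3 per group), vkg, a collagen IV chain, 46.2-fold (5.53, SE 0.43). Ostgamma, a subunit of the oligosaccharyltransferase, was 53-fold higher (5.73, SE 0.28). The membrane glycoprotein gene Gp150 was 45.4-fold higher, the membrane protein gene Serinc 42.6-fold, the lysosomal protease gene cathD 38.1-fold, yellow-f 38-fold and the lysosomal membrane protein gene Lamp1 36.9-fold. The long noncoding RNA CR42862 (51.3-fold) and CG2493 (47.2-fold) had an excess of similar size. On the cytoplasmic side the changes were smaller. The nuclear signal of eIF6, a factor bound to the large ribosomal subunit, was 10.9-fold lower (log2 change -3.45, SE 0.21), that of the Mediator subunit gene MED20 7.1-fold and that of e(y)2, a subunit of a histone acetyltransferase and of an mRNA export complex, 6.1-fold. PrBP was 5.5-fold lower, the augmin subunit gene wac and the succinate dehydrogenase assembly factor gene Sdhaf3 5.3-fold, and the complex I subunit gene ND-PDSW and the co-chaperone gene Sgt1 5.2-fold, with CG17996 at 7.8-fold and CG14818 at 6.5-fold. The adjusted p of the 20 genes so far named for this comparison was at most 3.46e-04 in limma, and all of them passed in every alternative.

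Of the lists fixed beforehand, secreted and extracellular matrix proteins had the smallest camera p, and plasmatocyte markers the highest median. Of 29 measured secreted and matrix members 24 were higher (25 adjusted over the list alone) and 0 lower, with a median log2 change of 3.63 (camera adjusted p = 2.14e-17, and adjusted p = 3.60e-04 with an estimated correlation). Besides Glt and vkg they included Hml (4.55, SE 0.41), a clotting protein of blood cells, and Idgf2 (4.48, SE 0.26), an imaginal disc growth factor. Markers of plasmatocytes, the phagocytic blood cells, had 9 of 10 members higher and a median of 3.66 (adjusted p = 8.23e-08, and 0.0022 as adjusted p with an estimated correlation). The phagocytic receptor gene eater (4.08, SE 0.28), Pxn (3.91, SE 0.19) and Pvr (3.68, SE 0.18) were among them. Several of these, such as Hml, vkg and Col4a1, are themselves secreted proteins, and the transcription factor gene srp had a log2 change of 0.01 (adjusted p = 0.9838).

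Genes of the endoplasmic reticulum and the secretory machinery went both ways. Of 26 measured, 16 were higher in the nuclear fraction and 7 lower, with a median of 2.13 (adjusted p = 1.06e-06, and adjusted p = 0.0022 with an estimated correlation). The protein disulfide isomerases CaBP1 (4.86, SE 0.14) and ERp60 (4.67, SE 0.15), OstDelta (4.13, SE 0.15) and the translocon channel gene Sec61alpha (4.08, SE 0.17) were highest. In the other direction lay genes whose products are cytosolic or inserted by their tails, among them Sec61gamma (-1.82, SE 0.2), Sec61beta (-1.76, SE 0.14) and the coat protein gene alphaCOP (-1.41, SE 0.15), named here after their values were seen.

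Other lists were lower in the nuclear fraction. All 52 called members of the 60 respiratory chain genes were lower (53 adjusted over the list alone), with a median of -1.35 (adjusted p = 1.92e-16), led by ND-PDSW, sun (-2.3, SE 0.2) and ATPsynE (-2.03, SE 0.23), both ATP synthase subunit genes. Mitochondrial ribosomal proteins had 55 of 64 lower and 0 higher (57 adjusted over the list alone), with a median of -1.29 (adjusted p = 4.42e-10) and mRpS18B at -2.3 (SE 0.39). Proteasome genes had 25 of 28 lower (median -1.25, adjusted p = 2.39e-09), with Prosbeta4 at -1.94 (SE 0.12) and Prosalpha6 at -1.9 (SE 0.15). Adjusted over the list alone, 26 proteasome genes were lower and 1 higher. Translation factors had 19 of 21 lower and 0 higher (19 and 1 adjusted over the list alone, median -1.15, adjusted p = 1.54e-07), with eIF3h at -1.88 (SE 0.19) after eIF6. Among ribosome biogenesis genes 13 of 21 were lower (14 adjusted over the list alone) and 1, Nop60B (1.81, SE 0.44), was higher, with a median of -1.11 (adjusted p = 7.04e-04). U2AF and early spliceosome genes had 13 of 21 lower and 1 higher (14 and 1 adjusted over the list alone), with a median of -1.13 (adjusted p = 5.68e-04), the core snRNP genes SmD2 (-1.8, SE 0.19) and SmB (-1.71, SE 0.19) lowest. With an estimated correlation the adjusted p of these 6 lists lay between 7.73e-04 and 0.0437. Cytosolic ribosomal proteins had 12 of 28 lower and 1 higher, with a median of -0.31 (adjusted p = 0.0224, but adjusted p = 0.1752 with an estimated correlation and adjusted p = 0.0699 without control cytoplasm replicate 1). This median was -0.82 on the values as deposited, -0.8 with arrays centred on their medians and -0.61 with quantiles within fractions.

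In all, 1417 probe sets were higher and 2114 lower in the nuclear fraction of control cells out of 8379 tested (adjusted p under 0.05), of which 1284 and 1453 changed at least 2-fold. The lists past the threshold with the preset correlation in this comparison had medians of the same sign under the 4 scalings of the arrays. Values are relative to the total signal of each fraction, so they do not give the share of a gene's mRNA in the nucleus.

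**Figure D2:**
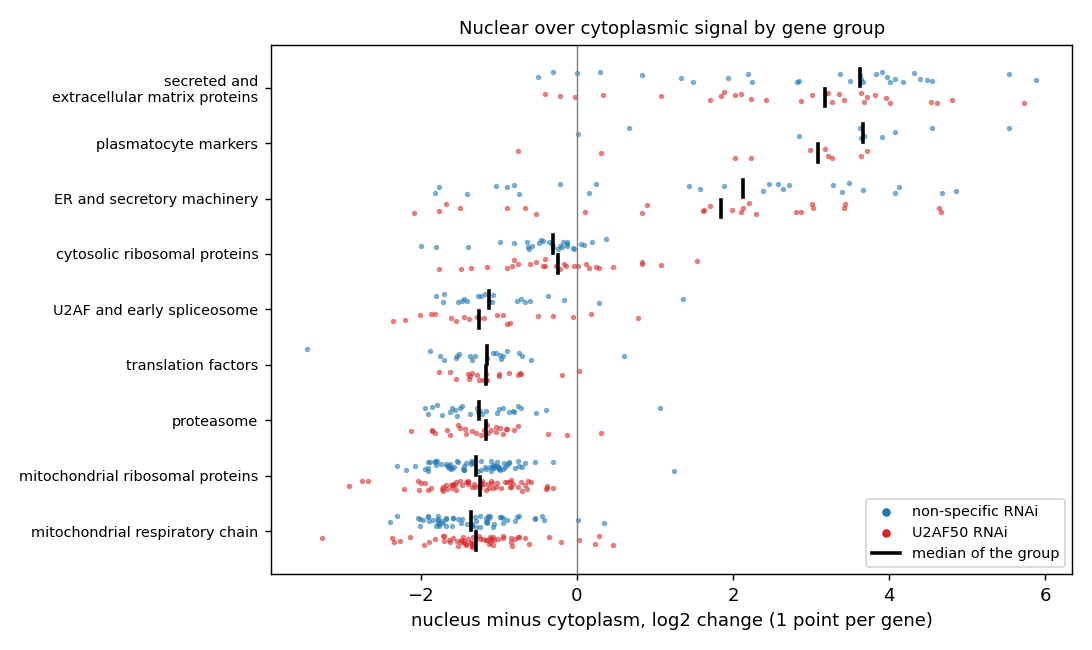
Log2 change between nuclear and cytoplasmic arrays for each measured member of 9 gene lists, under non-specific (blue) and U2AF50 (red) RNA interference, with 1 point per gene and a bar at the list's median. Secreted proteins and plasmatocyte markers lie mostly above 3 (medians 3.63 and 3.66 in the control), respiratory chain genes mostly below -1 (median -1.35), and the secretory machinery spreads over both sides.

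The same comparison in U2AF50-depleted cells gave 1503 probe sets higher and 2585 lower in the nuclear fraction. Glt was again highest among named genes (53.2-fold, log2 change 5.73, SE 0.3), followed by Gp150 (33.9-fold), O-fut1, an O-fucosyltransferase of the endoplasmic reticulum (29.5-fold), the laminin chain gene LanB1 (28-fold), orion (25.6-fold), cathD (25.4-fold), CaBP1 (25.3-fold) and ERp60 (25-fold), with CG2493 at 36-fold and CG1637 at 26.5-fold. Lower in the nuclear fraction were ND-PDSW (9.6-fold, log2 change -3.27, SE 0.37), the Mediator subunit genes MED28 (8.9-fold) and MED20 (6.8-fold), Mo25 (7.7-fold), mRpS24 (7.6-fold), Boh1 (7.5-fold), the replication factor gene Mcm10 (7.2-fold) and the glutathione transferase gene GstE7 (6.9-fold), with CG9175 at 11.7-fold and CG1236 at 9.3-fold. The adjusted p of these genes was at most 2.70e-05. Secreted and matrix proteins had 24 of 29 higher and 0 lower (median 3.18, adjusted p = 3.43e-17), plasmatocyte markers 8 of 10 higher and 1 lower (median 3.09, adjusted p = 5.62e-06) and the secretory machinery 18 of 26 higher and 6 lower (median 1.85, adjusted p = 2.98e-07). Respiratory chain genes had 52 of 60 lower and 0 higher (median -1.29, adjusted p = 1.39e-12). Mitochondrial ribosomal proteins had 54 of 64 lower and 0 higher (median -1.25, 57 lower adjusted over the list alone) and proteasome genes 25 of 28 lower and 0 higher (median -1.17). Translation factors had 19 of 21 lower (median -1.16), ribosome biogenesis genes 16 of 21 (median -1.19) and early spliceosome genes 16 of 21 lower with 1 higher (median -1.25, 17 lower adjusted over the list alone). With an estimated correlation the adjusted p of these 9 lists lay between 3.76e-04 and 0.0358. Export and exon junction factors had 16 of 27 lower (17 adjusted over the list alone, median -0.93, adjusted p = 0.0015, and adjusted p = 0.042 with an estimated correlation). SR protein and hnRNP genes had 11 of 18 lower and 1 higher (12 and 1 adjusted over the list alone, adjusted p = 0.0195, but adjusted p = 0.1052 with an estimated correlation), and cell cycle genes 19 of 33 lower and 0 higher (19 and 1 adjusted over the list alone, adjusted p = 0.0104, but adjusted p = 0.2369 with an estimated correlation and 0.1087 with the hybridisation controls as a covariate). U2af50 itself was higher in the nuclear fraction of depleted cells (log2 change 0.78, SE 0.26, adjusted p = 0.0196) and lower in that of the control (-1.18, SE 0.26, adjusted p = 0.0012). The call in depleted cells was lost in 8 of 26 alternatives, among them centring on array medians, quantiles within each fraction, and the fits without U2AF50 cytoplasm replicate 1 or 3 or nucleus replicate 1. U2af38 was lower in the nuclear fraction under both treatments (-0.77 and -0.86, SE 0.2 each).

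The 2 treatments shared no arrays in these comparisons, although the fit gave both the same estimate of spread per probe set. Of the probe sets higher in the nuclear fraction, 1167 were called under both, where independent lists would share 254, and of those lower, 1718 were shared against 652. Only 3 were higher in the control and lower in depleted cells, and 6 the other way. Across the 8379 probe sets, which are not independent replicates, the log2 changes correlated with r = 0.86 and rho = 0.78.

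In the cytoplasm, U2AF50 depletion was followed by a fall of respiratory chain mRNA. Of 60 measured genes of the chain 10 fell and 0 rose (23 fell adjusted over the list alone), with a median log2 change of -0.43 (camera adjusted p = 1.78e-15, and adjusted p = 0.0027 with an estimated correlation). With arrays centred on their medians the list's median was -0.14, where that of all tested probe sets was 0.21. Cytosolic ribosomal proteins had a median of -0.05 (camera adjusted p = 0.0589). Their median was -0.79 as deposited (adjusted p = 1.52e-16) and -0.56 with that centring (adjusted p = 1.01e-19). The respiratory chain list had -0.37 as deposited, so which of the 2 lists fell further depends on the scaling. SdhB, the iron-sulphur subunit of succinate dehydrogenase, fell 2.5-fold (log2 change -1.34, SE 0.18, adjusted p = 3.74e-04, n = 3 per group), and ND-MWFE of complex I fell 2.3-fold (-1.19, SE 0.15, adjusted p = 3.02e-04). ATPsynE (-0.97, SE 0.23) and ND-B14.5A (-0.85, SE 0.2) fell as well. The largest single falls were those of the ribosomal protein gene RpL28 (4.5-fold, log2 change -2.16, SE 0.22), the succinate dehydrogenase assembly gene Sirup (4.2-fold, -2.05, SE 0.16), CG13615 (3.6-fold) and U2af50, followed by Crtp (3.3-fold), the Arf GTPase-activating protein gene Asap (2.7-fold), the organic cation transporter gene Orct2 (2.3-fold) and CG3566 (2.5-fold).

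The largest rise was that of Nop60B, a pseudouridine synthase of the nucleolus (8.4-fold, log2 change 3.07, SE 0.44, adjusted p = 0.001). The glutathione transferase gene GstD5 rose 4.5-fold (2.18, SE 0.19, adjusted p = 4.32e-06), Ostgamma 4.2-fold (2.09, SE 0.28), the ABC transporter gene MRP 3.9-fold (1.97, SE 0.5), the nicotinamidase gene Naam 3.6-fold, TP53INP 3.6-fold, and Msr-110 and Serinc 3.5-fold, with CG18547 at 4.8-fold and CG43798 at 4.7-fold. Of 16 antimicrobial peptide and immune genes 4 rose (7 adjusted over the list alone) and 0 fell, namely the transcription factor gene dl (1.65, SE 0.34), DptB (0.98, SE 0.13), AttD (0.84, SE 0.16) and Mtk (0.75, SE 0.18), with a median of 0.41. Of 29 secreted and matrix proteins 3 rose (5 adjusted over the list alone), Tep4 (1.06, SE 0.14), Idgf6 (1.01, SE 0.14) and Nplp2 (0.9, SE 0.16), with a median of 0.28. Plasmatocyte markers had a median of 0.6 with 0 of 10 members called (1 higher adjusted over the list alone), crq (0.95), vkg (0.96) and Sr-CI (0.99) among the largest. Mitochondrial ribosomal proteins had a median of -0.11 with 0 of 64 called. The camera adjusted p of these 4 lists was 0.0204 for immune genes and plasmatocyte markers and 0.0428 for the others, and with an estimated correlation it was an adjusted p of 0.1237 for each of the 4. On the values as deposited and with arrays centred on their medians the calls of 3 of them ended. The medians were then 0.16 (adjusted p = 0.2036) and 0.38 (adjusted p = 0.1257) for secreted proteins and 0.62 (adjusted p = 0.0621) and 0.85 (adjusted p = 0.0559) for plasmatocyte markers. For mitochondrial ribosomal proteins they were -0.04 (adjusted p = 0.3823) and 0.19 (adjusted p = 0.6849). With that centring the median of all tested probe sets in the cytoplasm was 0.21, so the sign of 0.19 does not set this list above the rest. The immune median was 0.21 as deposited. Without single arrays the call of the secreted list ended for control cytoplasm replicate 3 (adjusted p = 0.1128), control nucleus replicate 3 (0.0508), U2AF50 cytoplasm replicate 1 (0.0546) and U2AF50 nucleus replicates 1 and 2 (0.0601 and 0.0695). That of the ribosomal list ended for control cytoplasm replicates 1 and 2 (0.0889 and 0.0685) and U2AF50 cytoplasm replicate 3 (0.0613), and also with the GAPDH ratio (0.5609) or the hybridisation controls (0.2753) as a covariate and without a filter (0.0633).

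Over all probe sets 148 rose and 67 fell in the cytoplasm, of which 79 and 20 changed at least 2-fold. RNA quality measures were set beside the treatment. The GAPDH 3' to 5' ratio was 2.9 ± 0.65 (SD, n = 3) in the depleted cytoplasm and 5.42 ± 2.17 in the control, a difference of -2.52 with an exact permutation p of 0.1 (2-sided), the smallest that 3 against 3 allow, and control replicate 1 stood at 7.91. The hybridisation controls differed by -1.16 on the log2 scale (12.34 ± 0.21 against 13.49 ± 1.1, SD, n = 3, exact permutation p = 0.2). The total of 215 calls became 31 with the GAPDH ratio and 61 with the hybridisation controls as a covariate. It was 85, 139 and 378 without control cytoplasm replicate 1, 2 and 3, 88, 55 and 52 without U2AF50 cytoplasm replicate 1, 2 and 3, and 131 without control nucleus replicate 1 or 3. Of the 19 named genes that rose or fell, U2af50 aside, 9 passed in every alternative, while MRP and Crtp failed in most.

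In the nucleus, U2AF50 depletion was followed by a rise of Ugt302K1, a UDP-glycosyltransferase gene (9.1-fold, log2 change 3.18, SE 0.45, adjusted p = 5.65e-04, n = 3 per group), and of eIF6 (8-fold, 3, SE 0.21, adjusted p = 2.75e-07). TP53INP rose 5.3-fold, the glutathione transferase genes GstE11 5.1-fold and GstD5 4.4-fold, the ABC transporter gene osy 5-fold, the lipase gene Lip4 4.9-fold and osk, the germ plasm organiser of the egg, 4.3-fold, with CG18547 at 8.3-fold and CG15784 at 7.5-fold. Sirup fell 8.7-fold (log2 change -3.11, SE 0.16, adjusted p = 1.86e-09). The Hedgehog co-receptor gene boi and Grip71, of the gamma-tubulin ring complex, fell 4.6-fold, S6KL and mst 4.3-fold, the exonuclease gene WRNexo 4-fold, the exosome subunit gene Rrp46 3.9-fold and HP1D3csd 3.7-fold, with CG1607 at 5-fold and CG12279 at 4.5-fold. Of the 20 named genes 14 passed in every alternative. The genes boi and Grip71 failed without any single one of the control nucleus replicates, WRNexo without replicate 3, HP1D3csd and CG1607 without replicate 1, and Grip71 also without U2AF50 nucleus replicate 2 or 3.

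Respiratory chain genes had 3 of 60 lower in the depleted nucleus (5 adjusted over the list alone) and 0 higher, namely ND-ASHI (-1.76, SE 0.3), ND-18 (-1.68, SE 0.39) and ATPsynC (-0.69, SE 0.16), with a median of -0.19 (camera adjusted p = 0.0017, but adjusted p = 0.2513 with an estimated correlation). With arrays centred on their medians this median was -0.43, against -0.14 in the cytoplasm. Under that scaling the medians of all tested probe sets were -0.15 in the nucleus and 0.21 in the cytoplasm. The 2 list medians therefore do not rank the fractions. Translation factors had a median of 0.17 with eIF6 as the 1 member called of 21, or 2 higher adjusted over the list alone (list adjusted p = 0.0066, but adjusted p = 0.2873 with an estimated correlation). The call of the list ended on the values as deposited (median 0.06, adjusted p = 0.2761), with arrays centred on their medians (-0.1, adjusted p = 0.6953) and without U2AF50 nucleus replicate 3 (adjusted p = 0.0587). Secreted and matrix proteins had 4 of 29 higher, among them Idgf4 (1.9, SE 0.48) and Tep4 (1.46, SE 0.14), and 1 lower, Col4a1 (-0.9, SE 0.19), or 6 and 3 adjusted over the list alone, with no call for the list (adjusted p = 0.222). Immune genes had 3 of 16 higher, Mtk (1.29, SE 0.18), AttD (1.18, SE 0.16) and DptB (0.79, SE 0.13), and 1 lower, spz (-0.65, SE 0.16), also with no call for the list (adjusted p = 0.1844). Over all probe sets 132 rose and 153 fell, 83 and 95 of them at least 2-fold. The GAPDH ratio was 6.19 ± 2.06 (SD, n = 3) in the depleted nucleus and 6.25 ± 1.76 in the control (exact permutation p = 0.9). The 285 calls became 125, 126 and 124 without control nucleus replicate 1, 2 and 3, 155 without the intensity trend, and 309 with arrays centred on their medians, of which 22.3% were higher against 46.3% before.

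The changes in the 2 fractions, which share no arrays, overlapped in part. Of the probe sets called in both, 47 rose in both, where independent lists would share 2.3 (Fisher's exact test p = 6.96e-51), and 12 fell in both against 1.2 (p = 2.25e-09), while 0 went opposite ways. Both contrasts used the same filter and the same estimate of spread per probe set, and Fisher's test takes probe sets as independent. Its p-values therefore do not measure replication between the fractions. TP53INP, GstD5, CG18547 and the immune genes Mtk, AttD and DptB rose in both, and Sirup fell in both. Osk rose in the cytoplasm as well (log2 change 1.71, SE 0.28). Across all 8379 probe sets the correlation was weak (r = 0.12, rho = 0.09, across genes, which are not independent replicates).

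**Figure D3:**
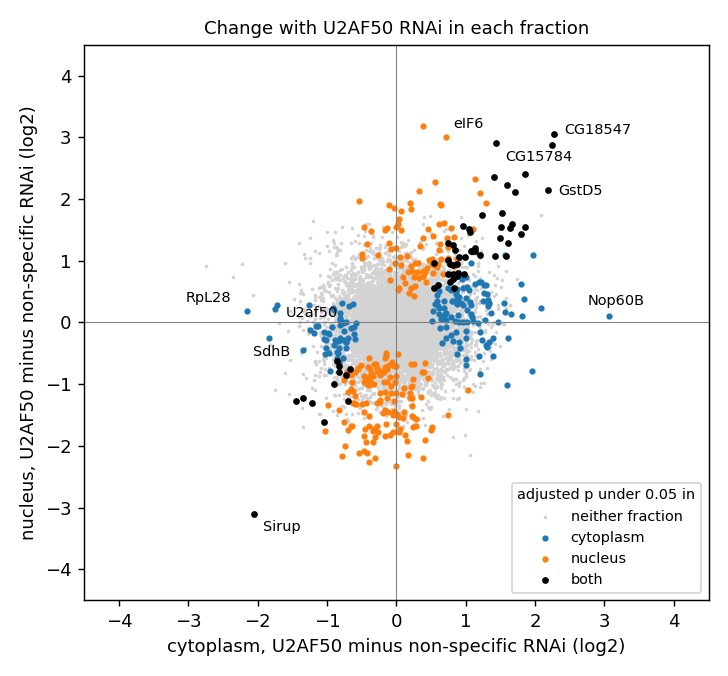
Log2 change with U2AF50 RNA interference in the cytoplasm (horizontal) and the nucleus (vertical), 1 point per probe set, coloured by the fraction in which limma's adjusted p was under 0.05. The 59 probe sets called in both lie in the upper right (47) or lower left (12), with Sirup lowest, while U2af50 and RpL28 fell in the cytoplasm only by this threshold.

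The interaction asked whether U2AF50 depletion changed the distribution of an mRNA between nucleus and cytoplasm. The ratio moved toward the nucleus for RpL28 (log2 change 2.34, SE 0.31, adjusted p = 0.0031), eIF6 (2.29, SE 0.3, adjusted p = 0.0031), U2af50, CG15784 (1.46, SE 0.2) and CG14903 (1.36, SE 0.25). It moved toward the cytoplasm for the secreted growth factor gene miple2 (-1.7, SE 0.32), the chaperone cofactor gene Sil1 (-1.7, SE 0.29), Swim, a secreted protein (-1.23, SE 0.22), CG3164 (-2.15, SE 0.4) and CG8026 (-1.95, SE 0.33). Over all probe sets 6 moved toward the nucleus and 8 toward the cytoplasm (adjusted p under 0.05), and 1091 had an unadjusted p under 0.05. Of 47 genes listed beforehand as intronless, which need no splicing, 27 were on the array and 11 were measured above the filter. Of these 11, 0 were called, with a median of -0.12 (camera adjusted p = 0.5). The largest among them was Ocho (1.57, adjusted p = 0.1528), the 1 member past the threshold when adjusted over the list alone. The simulated interaction recovered only 12% of log2 changes of 1 and 48% of changes of 2, so the lack of calls decides little. Plasmatocyte markers had a median of -0.73 with 0 of 10 called (camera adjusted p = 0.002, but adjusted p = 0.0835 with an estimated correlation). Respiratory chain genes had a median of 0.19 with 0 of 60 called (1 higher adjusted over the list alone, adjusted p = 0.0027, but adjusted p = 0.1787 with an estimated correlation). That call was lost on the values as deposited (median 0.13, adjusted p = 0.5435) and with the hybridisation controls as a covariate (adjusted p = 0.1554). It was also lost with arrays centred on their medians (adjusted p = 0.5641). The list's median was then -0.27, where that of all tested probe sets was -0.38. The count of 14 ranged from 3 to 83 as single arrays were left out and was 183 with arrays centred on their medians, and of the 10 named genes only eIF6 passed in all 25 alternatives.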

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

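The tests of a noisy nucleus, of exchanged nuclear arrays and of short housekeeping mRNA were chosen after the results were seen. The outcomes of the GAPDH test, of the fit without control cytoplasm replicate 1 and of the splits were set out before their results.

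A difference between fractions in the response to U2AF50 depletion drew attention to 14 probe sets. The interaction was 2.34 for RpL28, 2.29 for eIF6, 1.96 for U2af50, 1.46 for CG15784, 1.4 for a probe set with no single symbol and 1.36 for CG14903. It was -1.23 for Swim, -1.45 for the long noncoding RNA CR42862, -1.7 for Sil1 and miple2, -1.95 for CG8026, -2.15 for CG3164, and -2.07 and -2.75 for 2 more probe sets with no single symbol. RpL28 changed by -2.16 in the cytoplasm and 0.18 in the nucleus, eIF6 by 0.71 and 3. Of the 100 splits of the treatment labels drawn within each fraction, out of 200, 2 gave as many calls, the real one with 14 included. The highest other gave 17. This share lies under 0.05, but a split of mixed labels gave more calls than the real one. Mixed splits also carry real treatment differences in their spread, which can lower their counts. These splits therefore do not exclude chance. The count was 3 without control nucleus replicate 1, 6 and 4 without its replicates 2 and 3, 83 without control cytoplasm replicate 3, 9, 5 and 4 without U2AF50 cytoplasm replicates 1, 2 and 3, and 8, 8 and 34 without U2AF50 nucleus replicates 1, 2 and 3.

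Plasmatocyte markers (camera adjusted p = 0.002) and respiratory chain genes (adjusted p = 0.0027) differed between the fractions as lists, and with an estimated correlation their adjusted p was 0.0835 and 0.1787. Over 21 alternatives the adjusted p lay between 1.78e-04 and 0.0835 for the first and between 0.0011 and 0.5641 for the second. The camera direction of the second turned, without a call, when arrays were centred on their medians. Its median then went from 0.19 to -0.27, while that of all tested probe sets went from -0.11 to -0.38. The change of sign of the median thus came with a shift of all probe sets and does not set the list below them.

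U2af50 mRNA was lower in the cytoplasm and not called in the nucleus. Noise of the nuclear arrays would leave a fall of the cytoplasmic size within the nuclear interval. The 95% interval of the nuclear change ran from -0.33 to 0.76, above the cytoplasmic one from -2.29 to -1.2. Both intervals rest on 1 spread shared by the 4 groups, so they do not measure nuclear noise alone. The log2 values were 11.51, 10.86 and 10.79 in the depleted nucleus and 10.87, 10.88 and 10.78 in the control nucleus. None of the 3 depleted nuclear arrays thus showed a fall of the cytoplasmic size. An exchange of the nuclear arrays of the treatments would set the changes of the fractions against each other, and 0% of the 59 probe sets called in both went opposite ways. A hypothesis left by these tests is that RNA interference may act on the cytoplasmic mRNA and spare the nuclear pool. Signal from the added double-stranded RNA on this probe set was not tested and stays open.

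Respiratory chain mRNA was lower in the cytoplasm after depletion. With the GAPDH ratio as a covariate, which correlated with the treatment at r = -0.76 over the 6 cytoplasmic arrays, the list's median was -0.4. The camera p was 5.54e-16, and 3.07e-04 with an estimated correlation, so the list kept its fall with this covariate. Ratio and treatment went together in the cytoplasmic arrays, however, so the fit separates RNA integrity from treatment poorly. The same covariate took the calls in the cytoplasm from 215 to 31. The list lay below the mitochondrial ribosomal proteins, whose mRNAs are also short, by -0.31 (2-sided permutation p = 2.00e-05), and without control cytoplasm replicate 1 its median was -0.38 (camera p = 9.70e-16). That comparison used a single other list, so a fall of housekeeping mRNA in general stays open. Cytosolic ribosomal proteins had medians of -0.05 in the main fit, -0.06 with quantiles within fractions, -0.79 as deposited and -0.56 centred on medians. The respiratory chain list had -0.43, -0.39, -0.37 and -0.14, so which list fell further depends on the scaling. The size of the respiratory chain fall also depends on it, since the median was -0.14 with arrays centred on their medians, where that of all tested probe sets was 0.21. In the nucleus that scaling gave -0.43 for the list and -0.15 for all tested probe sets. An effect of U2AF50 depletion on these mRNAs, as the design names, stays open as a hypothesis that may hold beside other differences between the cytoplasmic preparations.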

How the results depend on the processing

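The fits with GAPDH and hybridisation covariates, the lists without single arrays and the lists on values as deposited were chosen after the data were seen. The fall of U2af50 in the cytoplasm kept its call in every setting (-1.49 to -1.82, and -2.07 to -1.53 without single arrays), and the calls between fractions stayed within 1.5 times of 3531 (3106 to 3717 without single arrays) and, but for 2669 with the hybridisation covariate, of 4088 (3433 to 4246). In the cytoplasm (215 calls, 68.8% higher) the count was 125 without a filter, 361 with arrays centred on their medians (87.8% higher), 43 without the trend, 99 at 2-fold, 52 at an adjusted p of 0.01, 31 and 61 with the GAPDH and hybridisation covariates, and 52 to 378 without single arrays. In the nucleus (285) it was 155 without the trend, 178 with only the arrays compared, 178 at 2-fold, 81 at 0.01 and 124 to 354 without single arrays. The interaction (14 calls, 42.9% higher) gave 25 with a pseudocount at the 40th percentile and 25 with a filter at the 60th, 7 without a filter, 35 as deposited (28.6% higher), 183 centred on medians (5.5% higher), 27 with quantiles within fractions (25.9% higher), 5 without the trend, 4 at 0.01, 3 with either covariate and 3 to 83 without single arrays. Lists past the threshold fell with an estimated correlation from 5 to 1 in the cytoplasm, from 2 to 0 in the nucleus and from 2 to 0 in the interaction, where they numbered 4 centred on medians, 4 as deposited and 1 with the hybridisation covariate. Without single arrays they numbered 1 to 3 in the nucleus. The camera direction of the respiratory chain list in the interaction turned, at adjusted p = 0.5641, when arrays were centred on their medians. Its median of -0.27 still lay above that of all tested probe sets (-0.38) under that scaling. Centring moved the median of all tested probe sets by -0.23 between depleted fractions, 0.17 in the cytoplasm and -0.27 in the interaction, as deposited values did by 0.14 and 0.12 in the first and last, and quantiles within fractions by -0.14 in both comparisons of fractions. Cytosolic ribosomal proteins depended on the scaling, with a median in the cytoplasm of -0.05 (adjusted p = 0.0589) against -0.79 as deposited (adjusted p = 1.52e-16) and -0.56 centred on medians (adjusted p = 1.01e-19). In the interaction it was 0.08 (adjusted p = 0.0938) against 0.89 (adjusted p = 8.04e-15) and 0.49 (adjusted p = 4.10e-14). The same numbers did not pair the samples, since of 18 pairs r lay between -0.089 and 0.135 and 1 exceeded 0.1, and an array correlated best with its own number in 16 of 36 cases (2 of 12 arrays in all other groups). With the replicate number as a block over all arrays the calls were 3534, 4086, 222, 267 and 20, and with blocks within treatments 3405, 3956 and 10. Alternatives other than a left-out array kept the call of a called named gene in 1145 cases and ended it in 94, and kept that of a called list in 274 and ended it in 31. They brought a list past the threshold in 29 cases and left it uncalled in 790. Without single arrays the call was kept in 1008 cases for genes and 397 for lists and ended in 108 and 11, and a list passed newly in 14. The cause was not tested. The planned test of all intronless genes was not run. Weak signals are limited by the pseudocount of 94.7, below which changes are compressed.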

Other observations

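The tests of the secretory machinery and of the scaling were chosen after the result was seen, and that of the V-ATPase before.

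Members of further lists were called between the fractions of control cells, while most of the lists as a whole were not past the threshold. Of 16 immune genes 7 were higher in the nuclear fraction and 5 lower, DptB (log2 change 3.77, SE 0.13), the Toll ligand gene spz (3.55, SE 0.16) and the receptor gene Tl (3.52, SE 0.41) among the former and AttD (-1.47, SE 0.16) and Mtk (-1.18, SE 0.18) among the latter (camera adjusted p = 0.2209). Of 9 apoptosis genes 2 were higher, the membrane-bound ligand gene egr (4.35, SE 0.28) and the caspase gene Dredd (1.3, SE 0.24), and 3 were lower (adjusted p = 0.7758). Of 8 ecdysone response genes the secreted protein gene ImpL2 (2.6, SE 0.14) and ImpE3 (3.37, SE 0.41) were higher and usp (-1.05, SE 0.36) lower (adjusted p = 0.2046). Of 4 lamellocyte markers the integrin gene mys (3.14, SE 0.17) and cher (2.08, SE 0.16) were higher (adjusted p = 0.0665). Of 27 mRNA export and exon junction genes 13 were lower and 0 higher (14 and 0 adjusted over the list alone, median -0.8, adjusted p = 0.0031, but adjusted p = 0.0548 with an estimated correlation), tsu (-1.7, SE 0.24) and Cbp20 (-1.49, SE 0.26) among them. Of 33 cell cycle genes 16 were lower and 1 higher (adjusted p = 0.0181, but adjusted p = 0.2767 with an estimated correlation), with PCNA at -1.68 (SE 0.13). Of 18 SR protein and hnRNP genes 10 were lower and 2 higher, ps (4, SE 0.31) and tra (1.15, SE 0.33), with adjusted p = 0.189. All 3 measured muscle markers were lower, Act87E at -1.53 (SE 0.14), with adjusted p = 0.0356, but adjusted p = 0.1013 with an estimated correlation. That call also ended without control cytoplasm replicate 1 (0.0575), with arrays centred on their medians (0.0638), on the values as deposited (0.0624) and without a filter (0.2085).

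Of 11 measured genes among those listed beforehand as intronless 4 were lower in the nuclear fraction and 1 higher (adjusted p = 0.8002). Of 11 RNA interference factors 4 were lower in the nuclear fraction (adjusted p = 0.2525), of 18 JNK and stress genes 5, GstD1 lowest (-1.52, SE 0.14, adjusted p of the list 0.3695), of 6 heat shock genes 1, Hsp27 (-0.87, SE 0.3, list 0.958), and of 7 Notch targets 1 (list 0.907), both 0 adjusted over the list alone, of 5 germline markers 1 lower and 1 higher, osk (1.26, SE 0.28, list 0.907), and of 4 fat body markers 0 (list 0.907). Among lists too small to test, the 2 measured members of the histone list were lower, the histone variant gene His2Av (-1.19) and Slbp (-1.44), whose product binds histone mRNA, and 0 of 2 neuronal and 0 of 2 crystal cell markers were called. His2Av also fell with U2AF50 depletion in the cytoplasm (-0.82, SE 0.13, adjusted p = 0.0016) and the nucleus (-0.7, SE 0.13, adjusted p = 0.0042). Beside it, p53 rose in the cytoplasm (1.14, SE 0.23, adjusted p = 0.0131), and RnrL, a ribonucleotide reductase subunit, rose in the nucleus (0.94, SE 0.17, adjusted p = 0.0045). RpS29 rose in both, by 1.51 (SE 0.22) and 1.55 (SE 0.22).

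The mRNA of secretory proteins was higher in the nuclear fraction, which could come from endoplasmic reticulum kept with the nuclei during hypotonic lysis, with its bound ribosomes. That explanation sets apart subunits of 1 complex by where they are made. The 10 membrane-spanning V-ATPase subunits had a median of 1.85 against -1.14 for the 8 cytosolic ones, a difference of 2.98. The 2-sided exact permutation p was 0.0038 over genes, which are not independent replicates. Of these subunits Vha16-5 (-0.23), VhaM9.7-a (0.05), VhaM9.7-b (0.28) and Vha26 (0.38) were not called. Within the secretory machinery, members inserted by the translocon lay 3.69 above cytosolic or tail-anchored ones, but that split was made after its members had been seen to go both ways and decides nothing. Of the 17 translocon-inserted members 16 were higher, while Hsc70-3 was not called (0.15, limma adjusted p = 0.5906). Among the antimicrobial peptide genes named above, DptB was higher in the nuclear fraction, but AttD and Mtk were lower. Scaling between the fractions argues little, since the lowest median of the secreted list over the 4 scalings was 3.48. The V-ATPase classes go with retained endoplasmic reticulum as a candidate explanation. In control cells 9 of 10 cell surface receptors and integrins were also higher and 0 lower (median 2.61). Of 8 cytosolic glycolytic enzymes 7 were lower and 0 higher (median -1.49). These 2 classes were given no test of their own. Retention of the mRNA of secretory proteins inside the nucleus was not tested and stays open.

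For the 4 contrasts of 3 against 3 arrays, 10 splits are too few for a share under 0.05. The real split was the 1 with as many calls in each. It gave 3531 and 4088 calls between the fractions in control and depleted cells, where the highest other split gave 0 in both, and 215 and 285 with depletion in the cytoplasm and the nucleus, where the highest other gave 1 in both. The other splits mix fractions or treatments within a group, so the real differences enter their spread and keep their counts low. These counts therefore say little about chance.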
